A study of Mus musculus with 45 samples.

How the data were processed

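Mouse heart development was followed on 45 Affymetrix arrays, 3 in each of 15 groups. Per the labels' protocols, RNA was taken from R1 embryonic stem cells and from tissue of CD1 mice, whole embryos at E7.5, heart tubes at E8.5, and left and right ventricles at 6 later stages. Day 3 and adult hearts were frozen and pulverised before extraction, and biotin-labelled cRNA was made from total RNA. Samples were grouped by stage and ventricle as their labels state.

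The deposited values were log2 expression values per probe set, made by the authors with RMA (robust multi-array average, which corrects background, normalizes by quantiles and summarises probes), per the submitters' processing notes. The version of RMA was not given in the sources used here. The table held 45101 probe sets, 64 of them controls, with values from 2.07 to 15.2. Array medians were 5.35 to 5.47, and sorted values of the arrays differed by at most 0.218 and by 0.0407 on average, so a change shared by most genes would be removed from these values. No detection calls were used, and 0 pairs of arrays held identical values. RMA compresses differences near background, so that fold changes of dim genes are understated.

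Probe sets were named from the platform annotation, which listed 35890 of them. Of these 34945 had 1 gene symbol and 932 several, and 9160 probe sets were unnamed or had no listed gene. Of the first, 34754 matched a mouse RefSeq gene (GRCm38.p6 names), and no coordinates were used. For each of 18193 genes, 9010 of which had several probe sets, the probe set with the highest mean over all arrays was used. Among the genes named in the text, probe sets of Camk2d (E7.5), Rora (E8.5), Gnas (E12.5), Afp and Dlst (day 3), Hbb-b2, Tnni2, Mycn and Igf2bp1 (adult), Meis2 and Mylk (ventricles at E14.5) and H2-D1 (ventricles at E18.5) were called in opposite directions.

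Tests were two-sided, in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05 for the adjusted p. For the stage steps, left and right ventricle of the same number were averaged first, since they can come from the same hearts, and 27 values of 9 stages were fitted together (18 residual degrees of freedom). Left was set against right in a fit of all 45 arrays as 15 groups (30 residual degrees of freedom), at each of 6 stages, as their mean, and as an F-test of whether the difference depended on the stage (5 degrees of freedom). Gene lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over all lists and steps or over all lists and ventricle comparisons. Each was tested again with an estimated correlation, which is stricter. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

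The groups, tests, alternatives, 47 gene lists and the rule for naming genes were fixed before the data were examined. Of the lists 45 were tested, and those of housekeeping and sex-linked genes served as checks. Of the listed genes 61 had no match and were not analysed here, T (brachyury) among them, and 743 were matched. The rule named, for each step, the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap. It named up to 6 genes per direction in the same way at each ventricle stage, up to 10 per direction for their mean (same direction at 5 or more stages), and the 10 smallest p of the F-test. It added the 4 members with the largest changes among the called members of each list described, and fixed genes given whatever their values. Predicted genes, clone names, probe sets with several genes and olfactory or vomeronasal receptors were passed over.

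The alternatives were a trended robust eBayes, fits of only the groups compared, a filter for genes above the median of all values in at least 3 arrays, other ways to combine probe sets, scaling of each array to the housekeeping list, stricter thresholds, single ventricles, each array left out in turn, and a replicate block. Same-numbered left and right ventricles deviated together at E12.5, where the correlations of their deviations from the group means were 0.271, 0.321 and 0.369 over all genes, each over 0.1. At the other stages at least 1 of 3 was not, though at day 3 all were over genes above the median (0.415, 0.125 and 0.254). The pairing at E12.5 thus comes from the data, and the labels do not state it. An array was marked, after the data were seen, where the mean of a list of another tissue (16 of the fixed lists and 5 added ones) lay over 1.5 log2 units above the other replicates of its group. This marked 6 arrays, and the comparisons were repeated without them.

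In a test on simulated data, 200 of 18193 genes were changed. For E14.5 against E12.5, 61.2% of changes of 0.5, 98.5% of 1 and 100% of 2 (log2) were recovered, with 8 of 181 calls false. For left against right at E12.5 the shares were 53.7%, 94.0% and 100%, with 10 of 175 calls false. E18.5 and the adult, of larger spread, were not simulated.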

Results

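Gene expression was measured on 45 microarrays that followed mouse heart development from embryonic stem cells (ESC) of the R1 line to the adult ventricle. Of the 15 groups of 3 arrays, 1 each held ESC, whole embryos at embryonic day 7.5 (E7.5) and heart tubes at E8.5. The others held left and right ventricles dissected separately at E9.5, E12.5, E14.5 and E18.5, 3 days after birth (day 3) and in the adult. The replicates were described as biological. A replicate held 30 to 50 embryos or hearts up to E9.5, 10 to 20 hearts at E12.5 and E14.5, 3 to 5 hearts at E18.5, and 1 heart at day 3 and in the adult. The number of arrays limited the precision. Each stage was set against the preceding one, and the left ventricle against the right from E9.5 on. Differences are on the log2 scale (n = 3 per group), so that a value of 1 is a 2-fold difference. The SE given with them came from the limma fit, which shares 1 estimate of a gene's spread over all groups. It is not the spread of the arrays compared, and understates it where single arrays stand apart. For each gene list, the counts of members that passed the test over all 18193 genes are given, and where the counts adjusted over the list alone differed they are added, with the main direction first.

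A set of genes fixed beforehand outlined the course (mean ± SD of 3). Pou5f1, a transcription factor of pluripotent cells, fell from 13.76 ± 0.10 in ESC to 12.26 ± 0.44 in the E7.5 embryo and 4.19 ± 0.09 in the E8.5 heart tube. Nanog fell from 11.61 ± 0.12 to 7.47 ± 0.78 and 3.12 ± 0.14. The cardiac transcription factor gene Nkx2-5 stood at 5.82 ± 0.44 in the E7.5 embryo and 10.22 ± 0.12 in the heart tube, and then between 9.06 ± 0.11 in the adult and 9.74 ± 0.07 at E9.5. Gata4 lay between 7.64 ± 0.13 at E14.5 and 8.39 ± 0.13 at day 3 from the heart tube on. The myosin genes Myh7 and Myh6 stood at 14.35 ± 0.11 and 13.58 ± 0.24 in the heart tube. Myh6 then fell to 11.72 ± 0.11 at E14.5 and rose to 13.82 ± 0.23 at E18.5 and 14.91 ± 0.06 in the adult. In contrast, Myh7 stood at 14.48 ± 0.10 at E18.5 and fell to 12.35 ± 0.24 at day 3 and 11.33 ± 0.45 in the adult. Tnni1, the slow skeletal troponin I of the fetal heart, fell from 14.13 ± 0.04 at day 3 to 5.18 ± 0.29 in the adult. The cardiac troponin I gene Tnni3 rose from 11.44 ± 0.16 in the heart tube to 14.20 ± 0.02 at E18.5. The ventricular light chain gene Myl2 was at 14.79 ± 0.03 at E9.5 and 14.98 ± 0.01 in the adult. The atrial light chain gene Myl7 fell from 12.58 ± 0.18 at E18.5 to 10.20 ± 0.22 at day 3, and its adult value of 8.61 ± 2.25 had a wide spread. Mki67, a marker of dividing cells, was 10.64 ± 0.04 in ESC, 9.75 ± 0.10 at E18.5 and 9.82 ± 0.12 at day 3, and fell to 5.62 ± 0.32 in the adult.

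**Figure D1:**
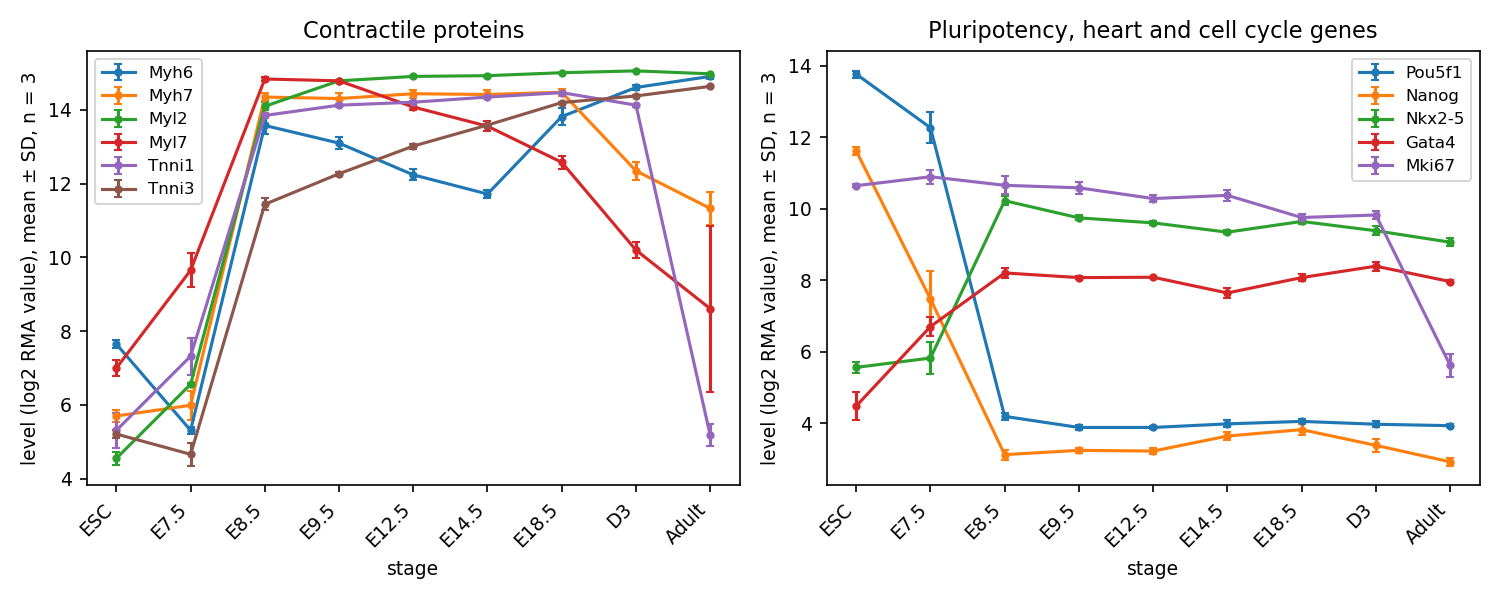
Levels of 11 genes (log2 RMA value) by stage as mean ± SD of 3 replicates, with left and right ventricle averaged from E9.5 on. Contractile protein genes are in the left panel, where Tnni1 drops to 5.18 ± 0.29 in the adult, and pluripotency, heart and cell cycle genes in the right.

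From ESC to the E7.5 embryo, most listed stem cell genes fell and all listed visceral endoderm genes rose. With R1 cells set against whole CD1 embryos, stage cannot be told apart from source, culture or tissue. The genes with the largest rises encode the apolipoproteins Apoc2 (8.60 ± 0.67), Apob (7.67 ± 0.61) and Apoa1 (7.42 ± 0.63) and the glucose transporter Slc2a2 (7.46 ± 0.64). They were followed by genes of the carrier proteins Rbp4 (7.23 ± 0.55) and Ttr (7.08 ± 0.50), the receptor Cubn (7.32 ± 0.57) and the homeobox factor Hoxb1 (6.63 ± 0.25). The largest falls were those of Gbp2b (-8.49 ± 0.09), Gbp2 (-8.12 ± 0.22) and Gbp3 (-6.36 ± 0.19), which encode guanylate-binding proteins, of Morc1 (-8.00 ± 0.09) and of the stem cell genes Dppa5a (-6.67 ± 0.14), Tdgf1 (-6.46 ± 0.51), Zfp42 (-6.42 ± 0.44) and Fbxo15 (-5.84 ± 0.13). Their adjusted p in limma ran from 2.25e-26 (Gbp2b) to 7.87e-10 (Slc2a2).

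Of the pluripotency genes, 22 of 26 fell, 3 rose and 1 was not called (camera adjusted p = 1.10e-13). Among markers of visceral endoderm, the layer that lines the yolk sac, 18 of 18 rose (camera adjusted p = 1.10e-13, adjusted p = 0.136 with an estimated correlation). Of the cardiac transcription factors, 17 of 24 rose, 2 fell and 5 were not called (camera adjusted p = 1.07e-07), with Irx3 (6.61 ± 0.13), Irx5 (5.37 ± 0.19) and Hand2 (4.95 ± 0.14) highest among the rises. In the list of Wnt, BMP, Notch and FGF pathway genes, 19 of 38 rose, 6 fell and 13 were not called (20 and 6 adjusted over the list alone, camera adjusted p = 0.002), led by Bmp5 (3.67 ± 0.15), Dll1 (3.38 ± 0.14) and Dkk1 (3.33 ± 0.11). Of the imprinted growth genes, 10 of 14 rose, 2 fell and 2 were not called (camera adjusted p = 6.73e-04), and Igf2, a fetal growth factor, rose by 3.21 ± 0.15. Of the genes induced by low oxygen, 10 of 16 rose, 1 fell and 5 were not called (camera adjusted p = 0.001), led by Adm (2.05 ± 0.29) and P4ha1 (1.53 ± 0.11). Of the immediate early genes, which respond to growth factors and handling, 16 of 18 fell and 2 were not called (camera adjusted p = 1.59e-11), including Klf2 (-5.25 ± 0.17) and Egr1 (-3.74 ± 0.19).

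In all, 8993 of 18193 genes were called (4414 higher, 4579 lower), 2119 of them with at least a 2-fold difference, and 14 of 45 gene lists were called, 7 also with an estimated correlation. When each array was scaled to a list of housekeeping genes, the median of all genes moved by 0.16 and 69.6% of the called genes were rises, against 49.1% without that scaling. Markers of decidua and trophoblast lay 3.72 above the mean of the other replicates in replicate 2 of the E7.5 embryos.

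From the E7.5 embryo to the E8.5 heart tube, most listed genes of calcium handling in heart muscle rose and most listed gastrulation genes fell. Here and at the next step, to ventricles, stage cannot be told apart from the change of tissue taken. The largest rises were those of Smpx (9.45 ± 0.09), Ankrd1 (9.37 ± 0.15), the giant sarcomere protein gene Ttn and the natriuretic peptide gene Nppa (8.86 ± 0.36). They were followed by Myh7 (8.36 ± 0.18), Myh6 (8.27 ± 0.12), the myosin chaperone gene Unc45b (8.22 ± 0.14) and the embryonic globin gene Hbb-y (8.1 ± 0.22). Pou5f1 (-8.07 ± 0.13) and Eras (-6.23 ± 0.12), both known from stem cells, led the falls. Behind them stood Zic5 (-5.72 ± 0.14), Zic2 (-5.61 ± 0.20), the caudal homeobox genes Cdx2 (-5.42 ± 0.15) and Cdx1 (-5.19 ± 0.12), and Apoc2 (-5.32 ± 0.67) and Slc2a2 (-5.0 ± 0.64). Adjusted p in limma ran from 4.32e-28 (Smpx) to 5.82e-07 (Slc2a2).

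Of the sarcomere and Z-disc genes, 24 of 26 rose, 1 fell and 1 was not called (camera adjusted p = 1.80e-30). Of the fetal sarcomere isoforms, 12 of 12 rose (camera adjusted p = 2.97e-16). Of the calcium-handling genes, 17 of 20 rose and 3 were not called (camera adjusted p = 7.79e-16), including Trdn (6.84 ± 0.13), Casq1 (6.43 ± 0.20) and the ryanodine receptor gene Ryr2 (6.08 ± 0.15). Of the cardiac transcription factors, 20 of 24 rose, 3 fell and 1 was not called (20 and 4 adjusted over the list alone, camera adjusted p = 4.97e-15), with Smyd1 (7.48 ± 0.14), Myocd (5.32 ± 0.17) and Nkx2-5 (4.40 ± 0.13) ahead. Of the electron transport chain genes, 35 of 38 rose and 3 were not called (camera adjusted p = 8.05e-11), with the muscle isoforms Cox7a1 (3.15 ± 0.15) and Cox6a2 (3.15 ± 0.08) as the largest. Of the smooth muscle and pericyte markers, 12 of 15 rose and 3 were not called (13 and 0 adjusted over the list alone, camera adjusted p = 2.48e-10), with Cnn1 (5.20 ± 0.21) and Acta2 (5.19 ± 0.17) ahead. For endothelial and endocardial markers, 21 of 24 rose, 2 fell and 1 was not called (camera adjusted p = 1.06e-11), led by Emcn (3.83 ± 0.18) and Plvap (3.74 ± 0.16). Among genes of the primitive streak and early mesoderm, 19 of 23 fell, 1 rose and 3 were not called (20 and 1 adjusted over the list alone, camera adjusted p = 8.98e-11, adjusted p = 0.062 with an estimated correlation). Among visceral endoderm markers, 18 of 18 fell (camera adjusted p = 1.69e-08, adjusted p = 0.286 with an estimated correlation). Among DNA replication genes, 28 of 30 fell and 2 were not called (29 and 0 adjusted over the list alone, camera adjusted p = 1.79e-08, adjusted p = 0.07 with an estimated correlation).

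The test called 8839 genes (3719 higher, 5120 lower), 1919 of them with at least a 2-fold difference. Of 45 lists 29 were called, 13 also with an estimated correlation. In replicate 2 of the heart tubes, visceral endoderm markers lay 2.47 above the mean of the other replicates.

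From the E8.5 heart tube to the E9.5 ventricles, most listed genes of mitochondrial energy production rose and most listed foregut markers fell. The largest rises were those of the retinoic acid enzyme gene Aldh1a1 (4.08 ± 0.19), the calcium pump regulator gene Pln (3.66 ± 0.14), the Z-disc gene Myoz2 (3.63 ± 0.16) and Upk3b (3.42 ± 0.30). Tm4sf1 (3.41 ± 0.13), Tmem71 (3.33 ± 0.10), the platelet factor gene Pf4 (3.29 ± 0.22) and the muscle caveolin gene Cav3 (3.21 ± 0.15) came next. Falls were largest for the epithelial cadherin gene Cdh1 (-4.78 ± 0.37), Spink1 (-4.62 ± 0.30), Arg1 (-4.46 ± 0.39) and Sox2 (-4.42 ± 0.29). Lower by less were Foxa1 (-4.33 ± 0.26), Cldn6 (-3.68 ± 0.19), the signalling gene Shh (-3.67 ± 0.17) and Otx2 (-3.59 ± 0.18). Limma gave these genes adjusted p from 5.61e-16 (Tmem71) to 1.02e-08 (Arg1).

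In the electron transport chain, 37 of 38 rose and 1 was not called (camera adjusted p = 1.69e-28), with Cox8b (1.85 ± 0.16) ahead. In the tricarboxylic acid cycle, 16 of 17 rose and 1 was not called (17 and 0 adjusted over the list alone, camera adjusted p = 1.58e-13). In fatty acid uptake and oxidation, 20 of 27 rose and 7 were not called (21 and 0 adjusted over the list alone, camera adjusted p = 4.32e-13), with Cpt1a (1.25 ± 0.18) as the largest. Of the foregut, lung and liver markers, 10 of 16 fell and 6 were not called (camera adjusted p = 7.90e-10). In replicate 2 of the heart tubes the mean of this list lay 0.87 and that of visceral endoderm 2.47 above the other replicates. Among genes known from the right ventricle and outflow side, 11 of 16 fell, 2 rose and 3 were not called (12 and 2 adjusted over the list alone, camera adjusted p = 3.59e-07), including Prdm1 (-3.14 ± 0.14), Tbx1 (-2.79 ± 0.17) and Fgf8 (-2.60 ± 0.15). Among oncofetal RNA-binding protein genes, 5 of 6 fell and 1 was not called (5 and 1 adjusted over the list alone, camera adjusted p = 1.15e-04), led by Lin28a (-2.72 ± 0.12) and Trim71 (-1.91 ± 0.10).

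In all 4900 genes were called (2337 higher, 2563 lower), 528 of them at least 2-fold, along with 20 of 45 lists, 8 also with an estimated correlation. Scaling to housekeeping genes moved the median of all genes by -0.13 and left 21.9% of the called genes as rises, against 47.7% without it. Decidua and trophoblast markers lay 1.62 and 2.11 above the other replicates in replicate 1 of the E9.5 left and right ventricles, and markers of the posterior trunk 1.86 in that of the right.

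From E9.5 to E12.5, most listed genes of connective tissue, leukocytes and fatty acid use rose in the ventricles, and most of the cell cycle and DNA replication fell. Rises were largest for the matrix proteoglycan gene Lum (5.20 ± 0.39), Snap91 (4.60 ± 0.19), Gtsf1 (4.54 ± 0.17) and the myoglobin gene Mb (4.51 ± 0.14). Then came the lysosomal protease gene Ctss (4.42 ± 0.39), Mgp (4.41 ± 0.61), Clca3a1 (4.22 ± 0.20) and the fatty acid binding protein gene Fabp4 (4.18 ± 0.67). The largest falls were those of Lin28a (-5.29 ± 0.12), the peptide hormone gene Cck (-4.90 ± 0.13), Plac8 (-3.81 ± 0.30) and Trim71 (-3.11 ± 0.10). Behind these came Prtg (-3.10 ± 0.15), Car4 (-3.04 ± 0.20), Snhg3 (-2.97 ± 0.20) and the cartilage collagen gene Col2a1 (-2.93 ± 0.22). In limma the adjusted p ran from 2.24e-19 (Lin28a) to 2.33e-05 (Fabp4).

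Of the fibroblast and matrix genes, 22 of 25 rose, 1 fell and 2 were not called (camera adjusted p = 7.28e-14), with Ogn (3.81 ± 0.10), Postn (3.52 ± 0.54) and Dcn (3.26 ± 0.29) next to Lum. Among leukocyte markers, 18 of 25 rose and 7 were not called (19 and 0 adjusted over the list alone, camera adjusted p = 8.06e-09, adjusted p = 0.058 with an estimated correlation), including C1qa (3.00 ± 0.16) and Csf1r (2.90 ± 0.36). In fatty acid uptake and oxidation, 23 of 27 rose and 4 were not called (camera adjusted p = 3.71e-11, adjusted p = 0.052 with an estimated correlation). In the cell cycle list, 23 of 33 fell and 10 were not called (25 and 0 adjusted over the list alone, camera adjusted p = 2.87e-09, adjusted p = 0.091 with an estimated correlation), led by Mybl2 (-1.32 ± 0.14). In the DNA replication list, 23 of 30 fell and 7 were not called (25 and 0 adjusted over the list alone, camera adjusted p = 9.66e-09, adjusted p = 0.067 with an estimated correlation). Among inhibitors of the cell cycle, 9 of 15 rose and 6 were not called (camera adjusted p = 0.005), with Cdkn2c (1.40 ± 0.16), Rbl2 (1.16 ± 0.12) and Rb1 (0.99 ± 0.11) in front. Among genes of the right ventricle and outflow side, 12 of 16 fell, 1 rose and 3 were not called (camera adjusted p = 3.68e-05). Of the oncofetal RNA-binding protein genes, 4 of 6 fell and 2 were not called (camera adjusted p = 3.51e-05).

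The test called 6936 genes (3655 higher, 3281 lower), 909 of them at least 2-fold, and 16 of 45 lists, 4 also with an estimated correlation. With the housekeeping scaling 65.5% of the called genes were rises, against 52.7% without it.

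From E12.5 to E14.5, the muscle creatine kinase gene and most listed genes of fatty acid use rose, and embryonic globin genes fell. The largest rises were those of Ckm, the muscle creatine kinase gene (3.38 ± 0.14), Fabp4 (3.23 ± 0.67), Ptgds (3.18 ± 0.19) and Aoc3 (3.05 ± 0.17). Behind them came the M-band gene Myom2 (3.03 ± 0.21), the capillary lipase anchor gene Gpihbp1 (2.90 ± 0.20), Fabp7 (2.58 ± 0.24) and the pericyte gene Rgs5 (2.55 ± 0.12). The largest falls were those of the embryonic globin genes Hbb-bh1 (-4.75 ± 0.85) and Hba-x (-3.18 ± 0.47) and the matrix genes Hapln1 (-2.77 ± 0.26) and Col9a1 (-1.93 ± 0.24). Next came St8sia1 (-1.76 ± 0.17), Gprin3 (-1.75 ± 0.14), the peptide gene Apela (-1.75 ± 0.28) and Hmga2 (-1.72 ± 0.15). Adjusted p in limma ran from 1.96e-13 (Ckm) to 0.002 (Fabp4), and the calls of Col9a1 and of Cthrc1, named next, were lost when only left ventricles were compared (adjusted p = 0.197 and 0.678).

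In fatty acid uptake and oxidation, 16 of 27 rose and 11 were not called (19 and 0 adjusted over the list alone, camera adjusted p = 2.60e-11, adjusted p = 0.05 with an estimated correlation), with the transporter gene Cd36 (1.36 ± 0.15) and the regulator gene Ppara (0.80 ± 0.13) following Fabp4. In the electron transport chain, 17 of 38 rose and 21 were not called (22 and 0 adjusted over the list alone, camera adjusted p = 4.34e-10), led by Cox8b (1.93 ± 0.16). Of the outflow tract and valve markers, 9 of 19 fell and 10 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 1.34e-04), including Cthrc1 (-1.04 ± 0.20) and Bmp4 (-0.74 ± 0.12). Of the imprinted growth genes, 6 of 14 fell, 1 rose and 7 were not called (camera adjusted p = 0.001), led by Cdkn1c (-1.05 ± 0.10), a cell cycle inhibitor. Of the oncofetal RNA-binding protein genes, 4 of 6 fell and 2 were not called (camera adjusted p = 4.76e-06).

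This step had 2415 calls (1307 higher, 1108 lower), 188 of them at least 2-fold, and 14 of 45 lists were called, 5 also with an estimated correlation. Single arrays moved the count, to 1417 without replicate 2 of E12.5 and 1344 without replicate 1 of E14.5. In replicate 2 of the E14.5 left ventricle, markers of epidermis lay 2.28 and of liver 2.21 above the other replicates, and those of visceral endoderm, of which 3 of 18 rose and 15 were not called (camera adjusted p = 0.002, adjusted p = 0.62 with an estimated correlation) at this step, lay 1.68 above them.

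From E14.5 to E18.5, most listed genes of mitochondrial energy production rose, and most of DNA replication, the cell cycle and embryonic red cells fell. The largest rises were those of the mitochondrial creatine kinase gene Ckmt2 (4.65 ± 0.18), Adhfe1 (3.83 ± 0.15), Myom2 (3.68 ± 0.21) and the potassium channel subunit gene Kcnip2 (3.39 ± 0.12). Next came Dhrs7c (3.16 ± 0.19), Higd1b (3.14 ± 0.15), Ankrd23 (2.92 ± 0.14) and the caveola gene Cavin4 (2.91 ± 0.10). Falls were led by the embryonic globin genes Hbb-y (-8.00 ± 0.22), Hba-x (-5.13 ± 0.47) and Hbb-bh1 (-3.41 ± 0.85) and by Micalcl (-5.11 ± 1.38). Behind them stood Hemgn (-3.14 ± 0.27), Egfl6 (-2.83 ± 0.17), Igfbp2 (-2.76 ± 0.19) and Rps6ka6 (-2.62 ± 0.12). Limma gave these genes adjusted p from 4.08e-17 (Hbb-y) to 0.006 (Micalcl).

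Of the electron transport chain genes, 38 of 38 rose (camera adjusted p = 1.03e-25). In the tricarboxylic acid cycle, 16 of 17 rose and 1 was not called (camera adjusted p = 1.06e-11, adjusted p = 0.067 with an estimated correlation). In fatty acid uptake and oxidation, 18 of 27 rose, 1 fell and 8 were not called (20 and 2 adjusted over the list alone, camera adjusted p = 8.05e-11, adjusted p = 0.056 with an estimated correlation). Of the sarcomere genes, 12 of 26 rose, 1 fell and 13 were not called (16 and 1 adjusted over the list alone, camera adjusted p = 3.39e-07), with Myh6 (2.11 ± 0.12) second to Myom2. Of the calcium-handling genes, 13 of 20 rose, 2 fell and 5 were not called (14 and 2 adjusted over the list alone, camera adjusted p = 8.72e-05, adjusted p = 0.08 with an estimated correlation), with S100a1 (1.33 ± 0.23) and Ryr2 (1.28 ± 0.15) ahead. Among DNA replication genes, 29 of 30 fell and 1 was not called (camera adjusted p = 1.74e-19), including Hells (-1.05 ± 0.10) and Cdc6 (-1.01 ± 0.08). In the cell cycle list, 24 of 33 fell and 9 were not called (27 and 0 adjusted over the list alone, camera adjusted p = 3.17e-09, adjusted p = 0.091 with an estimated correlation). Among embryonic red cell genes, 9 of 12 fell, 1 rose and 2 were not called (11 and 1 adjusted over the list alone, camera adjusted p = 8.74e-06, adjusted p = 0.167 with an estimated correlation). Their mean lay 1.73 above the other replicates in replicate 2 of the E14.5 left ventricle, and without the marked arrays the list was called as well (camera adjusted p = 3.01e-07). Of the imprinted growth genes, 11 of 14 fell and 3 were not called (12 and 0 adjusted over the list alone, camera adjusted p = 2.96e-04).

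The test called 5563 genes (2154 higher, 3409 lower), 506 of them at least 2-fold, together with 19 of 45 lists, 7 also with an estimated correlation.

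From E18.5 to day 3 after birth, most listed genes of fatty acid use rose while most genes induced by low oxygen fell. Rises were led by the gluconeogenic enzyme gene Fbp2 (3.35 ± 0.16), Angptl4 (3.31 ± 0.14), Pdk4, an inhibitor of glucose oxidation (3.00 ± 0.16), and Pcolce2 (2.76 ± 0.21). Next came Klhdc8a (2.64 ± 0.14), the lipid droplet gene Plin5 (2.62 ± 0.11), Steap4 (2.61 ± 0.14) and Tuba8 (2.60 ± 0.11). The largest falls were those of the liver genes Alb (-3.97 ± 0.37), Fga (-2.98 ± 0.48), Afp (-2.85 ± 0.61), Fgg (-2.65 ± 0.45) and Serpina1c (-2.54 ± 0.33). Falls were also large for Ankrd63 (-2.55 ± 0.19), the atrial light chain gene Myl4 (-2.51 ± 0.50) and the lymphocyte gene Rag1 (-2.40 ± 0.22). In limma the adjusted p ran from 1.64e-13 (Angptl4) to 0.002 (Afp). With right ventricles alone, the calls of Alb, Fga, Afp, Fgg, Serpina1c and Myl4 were lost (adjusted p = 0.081, 0.479, 0.483, 0.196, 0.085 and 0.056). Liver markers lay 3.38 above the other replicates in replicate 2 of the E18.5 left ventricle.

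In fatty acid uptake and oxidation, 22 of 27 rose, 2 fell and 3 were not called (23 and 2 adjusted over the list alone, camera adjusted p = 2.57e-24), with the uncoupling protein gene Ucp3 (2.44 ± 0.16) and the thioesterase genes Acot1 (2.11 ± 0.17) and Acot2 (1.69 ± 0.12) following Pdk4. Of the genes induced by low oxygen, 12 of 16 fell and 4 were not called (camera adjusted p = 8.08e-11), led by the glucose transporter gene Slc2a1 (-2.03 ± 0.10) and the oxygen sensor gene Egln3 (-1.56 ± 0.11). In glycolysis and glucose uptake, 9 of 18 fell, 3 rose and 6 were not called (camera adjusted p = 1.17e-04, adjusted p = 0.122 with an estimated correlation), with Slc2a3 (-1.64 ± 0.11) and Aldoc (-1.46 ± 0.10) next to Slc2a1. Among imprinted growth genes, 7 of 14 fell and 7 were not called (12 and 1 adjusted over the list alone, camera adjusted p = 9.27e-07), with Dlk1 (-2.08 ± 0.17) and Cdkn1c (-1.42 ± 0.10) as the largest. In the electron transport chain, 13 of 38 rose and 25 were not called (16 and 0 adjusted over the list alone, camera adjusted p = 5.18e-07, adjusted p = 0.091 with an estimated correlation). Of the fibroblast and matrix genes, 9 of 25 rose and 16 were not called (15 and 0 adjusted over the list alone, camera adjusted p = 2.53e-05, adjusted p = 0.266 with an estimated correlation), including Fbln2 (1.14 ± 0.16) and Eln (1.04 ± 0.25). Of the visceral endoderm markers, many of which are also liver genes, 5 of 18 fell and 13 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.62 with an estimated correlation). Their mean lay 2.05 above the other replicates in replicate 2 of the E18.5 left ventricle.

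Counts at this step were 3682 genes (1809 higher, 1873 lower), 285 of them at least 2-fold, and 16 of 45 lists, 3 also with an estimated correlation. With the housekeeping scaling 36.8% of the called genes were rises, against 49.1% without it.

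From day 3 to the adult, most listed cell division and imprinted growth genes fell in the ventricles, the former by large amounts. The largest falls were those of Tnni1 (-8.95 ± 0.19), Cited1 (-5.59 ± 0.18) and 6 genes of cell division. The latter were Depdc1a (-5.78 ± 0.12), Rrm2 (-5.69 ± 0.16), Birc5 (-5.56 ± 0.13), Cks2 (-5.48 ± 0.13), Cdca8 (-5.48 ± 0.09) and Ube2c (-5.44 ± 0.11). The largest rises were those of Plet1os (6.51 ± 0.12), the ketone body enzyme gene Bdh1 (6.47 ± 0.15), Cpxm2 (5.88 ± 0.15) and Art1 (4.86 ± 0.17). They were followed by the myosin kinase gene Mylk4 (4.85 ± 0.15), Ces1d (4.78 ± 0.19), the antigen presentation gene H2-Aa (4.64 ± 0.19) and the Z-disc gene Myot (4.22 ± 0.28). Adjusted p in limma ran from 8.70e-23 (Cdca8) to 7.58e-12 (Myot).

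Of the DNA replication genes, 30 of 30 fell (camera adjusted p = 1.69e-28). Of the cell cycle genes, 30 of 33 fell and 3 were not called (31 and 0 adjusted over the list alone, camera adjusted p = 6.00e-27), including Bub1 (-5.43 ± 0.10) and Ccnb2 (-4.89 ± 0.10). Among imprinted growth genes, 11 of 14 fell and 3 were not called (camera adjusted p = 1.34e-07), with Mest (-4.36 ± 0.08), Slc38a4 (-4.25 ± 0.10) and Igf2 (-3.87 ± 0.15) in front. Of the leukocyte markers, 20 of 25 rose, 2 fell and 3 were not called (camera adjusted p = 3.15e-07, adjusted p = 0.089 with an estimated correlation), with Lyz2 (2.55 ± 0.27) and C1qc (2.25 ± 0.13) among the rises and S100a9 (-2.32 ± 0.32) among the falls. Of the sarcomere genes, 9 of 26 rose and 17 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.301 with an estimated correlation), with Lmod2 (1.87 ± 0.11) and Tcap (1.82 ± 0.14) after Myot.

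Between these stages 8872 genes were called (4066 higher, 4806 lower), 1829 of them at least 2-fold, and 10 of 45 lists, 3 also with an estimated correlation. The housekeeping scaling moved the median of all genes by 0.17, and with it 67.8% of the called genes were rises, against 45.8% without it.

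**Figure D2:**
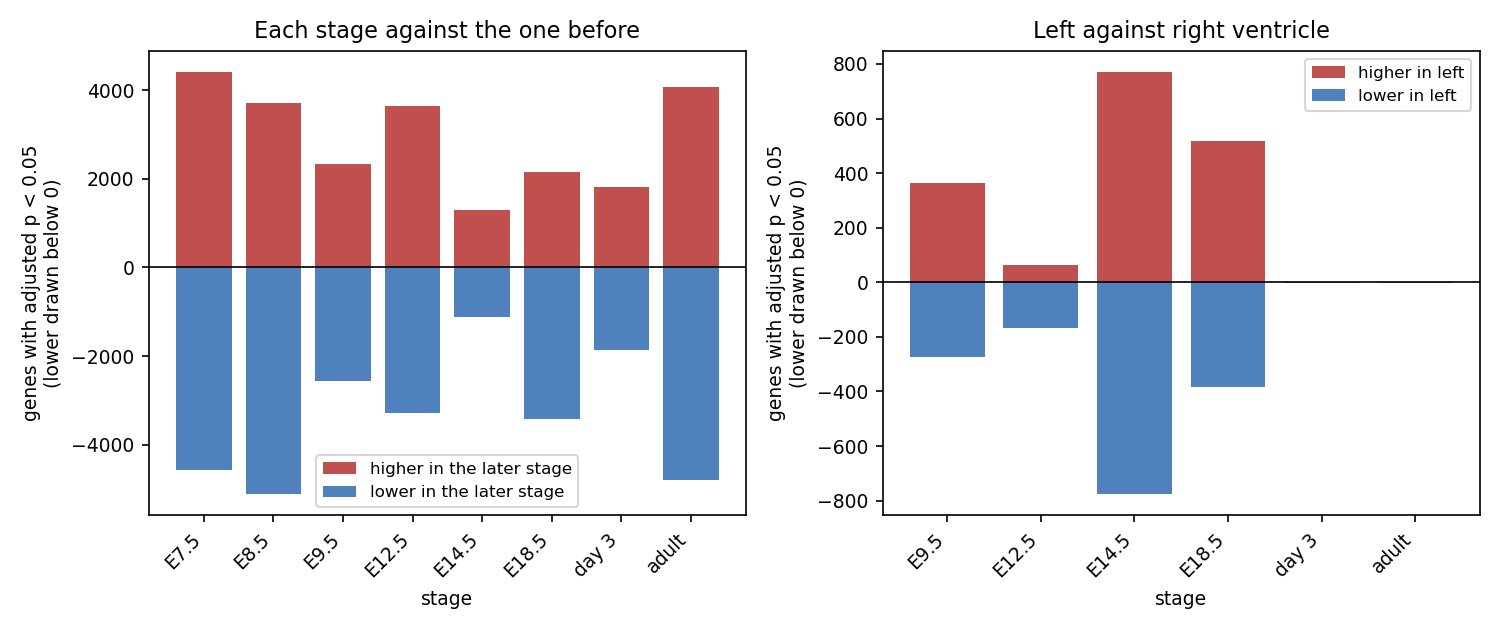
Genes with adjusted p under 0.05 in limma, for each stage against the preceding one in the left panel and for left against right ventricle in the right panel, with higher genes above and lower genes below 0. The steps range from 2415 genes at E14.5 to 8993 at E7.5, and the ventricle comparisons from 1 at day 3 to 1548 at E14.5.

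Between the ventricles at E9.5, the lists of outflow tract genes and of genes known from the right ventricle were lower in the left, and that of genes graded towards the left ventricle was higher there. The growth factor co-receptor gene Tdgf1 (-5.24 ± 0.43), the signalling gene Bmp4 (-3.05 ± 0.14), the matrix gene Tnc (-3.05 ± 0.23) and the neurotensin gene Nts (-3.02 ± 0.29) had the largest differences towards the right. Next came the precursor cell transcription factor gene Isl1 (-3.00 ± 0.18) and Masp1 (-2.54 ± 0.21). Gtsf1 (2.84 ± 0.23), the guidance cue gene Ntn1 (2.72 ± 0.22), Nlrp10 (2.47 ± 0.21), Cited1 (2.40 ± 0.19), Tmem163 (1.94 ± 0.24) and Map3k8 (1.76 ± 0.17) had the largest towards the left. Limma gave these genes adjusted p from 4.72e-18 (Bmp4) to 9.91e-07 (Tmem163). Tbx5 (1.41 ± 0.13), Gja5 (0.87 ± 0.19) and Hand1 (0.67 ± 0.13) were higher in the left. Fgf10 (-1.91 ± 0.16), Cck (-0.87 ± 0.15) and Hand2 (-0.47 ± 0.13) were lower, and the Nppa difference of 1.43 ± 0.49 was not called (adjusted p = 0.114).

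Of the genes known from the right ventricle and outflow side, 10 of 16 were lower in the left, 1 was higher in the left and 5 were not called (12 and 2 adjusted over the list alone, camera adjusted p = 3.19e-28). Of the genes graded towards the left ventricle, 4 of 8 were higher in the left and 4 were not called (5 and 0 adjusted over the list alone, camera adjusted p = 1.75e-10). Of the outflow tract and valve markers, 9 of 19 were lower in the left and 10 were not called (10 and 1 adjusted over the list alone, camera adjusted p = 1.11e-19), with Fgf8 (-2.43 ± 0.16) next to Bmp4 and Isl1. Of the trabecular genes, 5 of 15 were higher in the left and 10 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 6.52e-10), with Irx5 (1.26 ± 0.19) and Bmp10 (0.89 ± 0.15) after Cited1. In the Wnt, BMP, Notch and FGF list, 9 of 38 were lower in the left, 3 were higher in the left and 26 were not called (14 and 6 adjusted over the list alone, camera adjusted p = 5.78e-08), including Fgf8 and the Wnt inhibitor gene Dkk1 (-2.41 ± 0.12). Of the endothelial and endocardial markers, 3 of 24 were higher in the left and 21 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 1.93e-05, adjusted p = 0.318 with an estimated correlation), with Npr3 (1.37 ± 0.19) ahead.

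The count was 637 genes (364 higher and 273 lower in the left), 139 of them at least 2-fold, with 13 of 45 lists called, 5 also with an estimated correlation. It was 422 without the marked arrays (347 shared), 397 without replicate 2 of the left and 357 without replicate 1 of the right ventricle, which was marked. Without the marked arrays the calls of Gja5 (adjusted p = 0.062) and Hand2 (adjusted p = 0.072) were lost, and the Hand2 call was lost without any of 5 of the 6 arrays.

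At E12.5, the list of outflow tract and valve genes was lower in the left ventricle. The largest differences towards the right were those of the elastic fibre genes Fbln5 (-3.38 ± 0.29) and Eln (-3.31 ± 0.38), the Wnt modulator gene Sfrp2 (-3.01 ± 0.56) and Rgs5 (-2.93 ± 0.13). The interferon-inducible gene Iigp1 (-2.78 ± 0.22) and Col9a1 (-2.57 ± 0.32) came next. Towards the left they were those of Gtsf1 (2.39 ± 0.23), Chn2 (1.72 ± 0.17), Tfcp2l1 (1.67 ± 0.22), Tmem88b (1.5 ± 0.30), Ntn1 (1.47 ± 0.22) and Dclk3 (1.43 ± 0.19). In limma the adjusted p ran from 3.32e-18 (Rgs5) to 0.003 (Tmem88b). The atrial and trabecular connexin gene Gja5 (1.40 ± 0.19), Tbx5 (0.86 ± 0.13) and Hand1 (0.68 ± 0.13) were higher and Isl1 (-1.34 ± 0.18) lower in the left. Differences of Nppa (1.11 ± 0.49), Cited1 (0.65 ± 0.19), Hand2 (-0.32 ± 0.13), Fgf10 (-0.37 ± 0.16) and Cck (-0.15 ± 0.15) were not called (adjusted p from 0.081 for Cited1 to 0.956 for Cck).

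Of the outflow tract and valve markers, 9 of 19 were lower in the left and 10 were not called (13 and 0 adjusted over the list alone, camera adjusted p = 3.01e-26), including Cthrc1 (-2.17 ± 0.28), the Wnt amplifier gene Rspo3 (-1.60 ± 0.21) and Sema3c (-1.5 ± 0.17). Of the genes graded towards the left ventricle, 3 of 8 were higher in the left and 5 were not called (5 and 0 adjusted over the list alone, camera adjusted p = 6.37e-10). Of those known from the right and outflow side, 4 of 16 were lower in the left and 12 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 8.04e-09). In the Wnt, BMP, Notch and FGF list, 4 of 38 were lower in the left and 34 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 2.95e-07), with Bmp2 (-1.39 ± 0.23) and Bmp4 (-0.93 ± 0.14) ahead. These lists share members, as named for E9.5. Of the genes induced by low oxygen, 2 of 16 were lower in the left and 14 were not called (camera adjusted p = 2.06e-08), namely Egln3 (-1.0 ± 0.11) and Slc2a1 (-0.64 ± 0.12). Among fibroblast and matrix genes, 3 of 25 were lower in the left and 22 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 6.87e-07, adjusted p = 0.378 with an estimated correlation).

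The test called 230 genes (63 higher and 167 lower in the left), 86 of them at least 2-fold, and 12 of 45 lists, 5 also with an estimated correlation. A fit of the 6 arrays alone called 576 genes (209 shared), and 129 were called without replicate 1 of the left ventricle. The Tmem88b call was lost in the fit of the 6 arrays and without replicate 3 of the left ventricle (adjusted p = 0.114 and 0.108). At this stage same-numbered ventricles deviated together. With the number as a block, the list calls of ion channels (adjusted p = 0.015 without and 0.060 with the block) and skeletal muscle (0.035 and 0.119) were lost and that of endothelial markers (0.058 and 0.011) was gained. The skeletal muscle list, called as lower in the left, was the only called one whose median (0.01) and mean (-0.23) differed in sign.

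At E14.5, genes known from skeletal muscle and skin were among the largest differences towards the left ventricle samples. The largest differences towards the left were those of the angiotensin receptor gene Agtr2 (3.79 ± 0.47) and the skeletal muscle genes Myh3 (3.76 ± 0.52) and Tnnc2 (3.25 ± 0.46). They were followed by the keratinocyte gene Krtdap (3.06 ± 0.57), Cdh1 (2.86 ± 0.59) and the skin gene Dmkn (2.66 ± 0.85). Towards the right they were those of Dcpp1 (-2.91 ± 0.25), a gene named after a protein of salivary glands, the Wnt inhibitor gene Wif1 (-1.79 ± 0.35) and Tesc (-1.76 ± 0.25). Next came Ppp1r17 (-1.55 ± 0.21), Hapln1 (-1.54 ± 0.31) and Mybphl (-1.33 ± 0.43). Adjusted p in limma ran from 3.39e-09 (Dcpp1) to 0.046 (Mybphl). In replicate 2 of the left ventricle, markers of epidermis lay 2.28, of liver 2.21 and of embryonic red cells 1.73 above the other replicates. The mean of the skeletal muscle list was 6.33, 7.31 and 5.88 in replicates 1 to 3 of the left and 5.71 to 5.75 in the right. The Krtdap level was 6.99 ± 2.44 (SD) in the left against 3.92 ± 0.09 in the right. Of the genes given at each stage, Gja5 was called (0.71 ± 0.19). No call was made for Tbx5 (0.34 ± 0.13), Hand1 (0.15 ± 0.13), Hand2 (-0.32 ± 0.13), Nppa (0.25 ± 0.49), Cited1 (0.31 ± 0.19), Isl1 (-0.29 ± 0.18), Fgf10 (0.02 ± 0.16) or Cck (-0.14 ± 0.15) (adjusted p from 0.109 for Tbx5 to 0.969 for Fgf10).

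Of the skeletal muscle markers, 7 of 17 were higher in the left and 10 were not called (8 and 3 adjusted over the list alone, camera adjusted p = 1.95e-04, adjusted p = 0.367 with an estimated correlation), with Myog (1.89 ± 0.40) after Myh3 and Tnnc2. Of the fibroblast and matrix genes, 9 of 25 were higher in the left and 16 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 3.42e-08, adjusted p = 0.319 with an estimated correlation), with Col6a3 (1.67 ± 0.23) and Col1a1 (1.54 ± 0.25) ahead. In the electron transport chain, 10 of 38 were lower in the left and 28 were not called (19 and 0 adjusted over the list alone, camera adjusted p = 4.70e-08, adjusted p = 0.151 with an estimated correlation), led by Cox6a2 (-0.70 ± 0.08). In the cell cycle list, 5 of 33 were higher in the left and 28 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 4.86e-05, adjusted p = 0.41 with an estimated correlation), including Mki67 (1.07 ± 0.18). Of the imprinted growth genes, 4 of 14 were higher in the left and 10 were not called (camera adjusted p = 4.17e-05), with Dlk1 (1.33 ± 0.16) ahead. Among embryonic red cell genes, 2 of 12 were higher in the left and 10 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 6.49e-06, adjusted p = 0.378 with an estimated correlation), namely Slc4a1 (1.61 ± 0.38) and Alas2 (1.33 ± 0.38).

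In all 1548 genes were called (771 higher and 777 lower in the left). Of them 96 were at least 2-fold higher and 21 lower, with 13 of 45 lists called, 1 also with an estimated correlation. The count was 551 without the marked arrays (514 shared) and 509 in a fit of the 6 arrays alone. It was 445 and 928 without replicates 2 and 3 of the left, 564 and 673 without replicates 1 and 2 of the right ventricle. The calls of Dmkn and Mybphl were each lost without any of 4 of the 6 arrays, and those of Slc4a1, Alas2 and Myog without the marked arrays (adjusted p = 0.147, 0.280 and 0.062). That of Gja5 was lost without replicate 3 of the left or replicates 2 or 3 of the right ventricle, and those of Agtr2, Myh3, Krtdap, Cdh1 and Hapln1 in the fit of the 6 arrays (adjusted p = 0.056, 0.052, 0.119, 0.153 and 0.050).

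At E18.5, epicardial markers as a list and single genes known from liver were higher in the left ventricle samples. The largest differences towards the left were those of Fga (4.60 ± 0.74), Alb (4.54 ± 0.82), Afp (3.83 ± 0.91), Serpina1c (3.41 ± 0.62), Fgg (3.34 ± 0.71) and Apoa1 (2.86 ± 0.77), all known from liver. Towards the right they were those of Wif1 (-1.94 ± 0.35), Znf41-ps (-1.48 ± 0.44), the histocompatibility genes H2-D1 (-1.24 ± 0.33) and H2-K1 (-1.15 ± 0.33), the calcium store gene Casq1 (-1.19 ± 0.28) and the guidance receptor gene Robo1 (-1.18 ± 0.26). Limma gave these genes adjusted p from 2.32e-04 (Fga) to 0.045 (Znf41-ps). Alb stood at 11.02 ± 1.78 (SD) in the left and 6.48 ± 2.08 in the right. In replicate 2 of the left ventricle liver markers lay 3.38 and visceral endoderm markers 2.05 above the other replicates. None of Hand1 (0.18 ± 0.13), Hand2 (-0.05 ± 0.13), Tbx5 (0.16 ± 0.13), Nppa (0.53 ± 0.49), Gja5 (0.56 ± 0.19), Cited1 (0.17 ± 0.19), Isl1 (-0.19 ± 0.18), Fgf10 (-0.25 ± 0.16) and Cck (-0.19 ± 0.15) was called (adjusted p from 0.083 for Gja5 to 0.88 for Hand2).

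Of the epicardial markers, 9 of 15 were higher in the left and 6 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 3.29e-14), led by Lrrn4 (2.23 ± 0.37), Msln (2.04 ± 0.32) and Muc16 (1.85 ± 0.24). Of the leukocyte markers, 8 of 25 were higher in the left and 17 were not called (13 and 0 adjusted over the list alone, camera adjusted p = 4.93e-09, adjusted p = 0.151 with an estimated correlation). Of the thymus and lymphoid markers, 5 of 13 were higher in the left and 8 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 3.55e-05, adjusted p = 0.151 with an estimated correlation), with Rag1 (2.76 ± 0.45) ahead. In left replicates 1 to 3 the mean of this list was 5.75, 5.67 and 5.02 (4.74 to 4.99 in the right). Means of epicardial markers were 8.71, 8.71 and 8.0 (7.15 to 7.31), and of leukocyte markers 7.83, 7.78 and 7.29 (6.97 to 7.03). Of the visceral endoderm markers, many of them also liver genes, 7 of 18 were higher in the left and 11 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 2.08e-06, adjusted p = 0.453 with an estimated correlation). In the tricarboxylic acid cycle, 3 of 17 were lower in the left and 14 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 1.62e-07, adjusted p = 0.322 with an estimated correlation), and in glycolysis, 1 of 18 was lower in the left and 17 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 7.62e-07, adjusted p = 0.151 with an estimated correlation).

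The test called 900 genes (516 higher and 384 lower in the left), 138 at least 2-fold higher and 11 lower. It also called 17 of 45 lists, 1 also with an estimated correlation. Single arrays moved the count, to 373, 165 and 2754 without replicates 1, 2 and 3 of the left and to 322, 322 and 573 without replicates 1, 2 and 3 of the right ventricle. It was 279 without the marked arrays (255 shared) and 135 in a fit of the 6 arrays. Without replicate 2 of the left ventricle the calls of Afp, Apoa1, Fgg, Casq1, H2-D1, H2-K1, Znf41-ps and Robo1 were lost. Those of Alb, Fga, Serpina1c and Rag1 were lost in the fit of the 6 arrays, and H2-D1 turned to 0.41 with the mean of its probe sets.

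At day 3 a single gene was called between the ventricles, Dcpp1, which was lower in the left (-2.51 ± 0.25, limma adjusted p = 1.90e-07), at 5.58 ± 0.09 (SD) against 8.09 ± 0.62 in the right. Wif1 stood at 6.33 ± 0.21 and 8.05 ± 0.06 and Sln, a calcium pump regulator gene of the atria, at 4.90 ± 0.62 and 7.04 ± 0.54. Among the genes given at each stage, Nppa differed by 0.93 ± 0.49, Gja5 by -0.29 ± 0.19, Cck by -0.21 ± 0.15. Tbx5 differed by 0.16 ± 0.13, Hand1 by 0.16 ± 0.13, Isl1 by 0.10 ± 0.18, Fgf10 by 0.06 ± 0.16, Cited1 by -0.05 ± 0.19 and Hand2 by -0.01 ± 0.13, with none of the 9 called (adjusted p = 1 for each). Of 45 lists 4 were called, and 0 with an estimated correlation. The outflow tract and valve list was lower in the left (camera adjusted p = 0.011, adjusted p = 0.251 with an estimated correlation), with 0 of 19 members called over all genes and 3 lower adjusted over the list alone, and so was the list of the right ventricle and outflow side (camera adjusted p = 0.027, adjusted p = 0.096 with an estimated correlation), with 0 of 16 and 3. At an unadjusted p under 0.05 there were 580 genes, and the count of 1 became 2 with the replicate number as a block and 2 without replicate 1 of the right ventricle.

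In the adult 3 genes were called, all lower in the left, namely the cell division genes Cdca3 (-0.99 ± 0.13, limma adjusted p = 9.30e-05) and Ndc80 (-0.71 ± 0.10, adjusted p = 2.70e-04) and the gene Cnpy4 (-0.55 ± 0.10, adjusted p = 0.035). Hand1 (-0.22 ± 0.13), Nppa (-0.35 ± 0.49), Gja5 (0.24 ± 0.19), Isl1 (-0.11 ± 0.18), Cited1 (-0.07 ± 0.19), Fgf10 (-0.05 ± 0.16), Cck (0.07 ± 0.15), Hand2 (0.04 ± 0.13) and Tbx5 (-0.01 ± 0.13) were not called (adjusted p from 0.887 for Hand1 to 0.999 for Tbx5). Fibroblast and matrix genes as a list were lower in the left (camera adjusted p = 1.14e-07, adjusted p = 0.356 with an estimated correlation), and so were leukocyte markers (camera adjusted p = 3.71e-05, adjusted p = 0.378 with an estimated correlation) and atrial markers (camera adjusted p = 0.003, adjusted p = 0.307 with an estimated correlation). Their means in replicates 1 to 3 of the right ventricle were 9.98, 11.36 and 10.04 for fibroblast and matrix genes, 8.49, 8.93 and 8.55 for leukocyte and 7.09, 8.08 and 8.99 for atrial markers. In the left they were 9.97 to 10.24, 8.35 to 8.54 and 7.04 to 7.75. No member of these lists was called over all genes, and 4 of 15 atrial markers were lower adjusted over the list alone. Of 45 lists 8 were called, and 0 with an estimated correlation. At an unadjusted p under 0.05 there were 1127 genes. A limma fit of the 6 adult arrays called 0 genes, with 273 at an unadjusted p under 0.05. The Cdca3 call was lost with the mean of its probe sets (adjusted p = 0.496), those of Ndc80 and Cnpy4 with the replicate block (0.055 and 0.087), and that of Cnpy4 without replicate 1 of the left (0.168), replicate 2 of the right (0.162) or the marked arrays (0.073). The count was 6, 18 and 35 without replicates 1, 2 and 3 of the left and 98 and 52 without replicates 1 and 3 of the right ventricle.

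Averaged over the 6 stages, the list of outflow tract genes was lower in the left ventricle and that of trabecular genes higher. The largest differences towards the right were those of Sln (-1.70 ± 0.35), Wif1 (-1.41 ± 0.14), Sfrp2 (-1.17 ± 0.23), Rspo3 (-0.98 ± 0.09) and Col9a1 (-0.95 ± 0.13). Next came Bmp4 (-0.82 ± 0.06), Shisa2 (-0.81 ± 0.11), Isl1 (-0.80 ± 0.08), Scara3 (-0.79 ± 0.11) and Ddc (-0.78 ± 0.12). Towards the left were Gtsf1 (1.51 ± 0.09), Ntn1 (0.94 ± 0.09), Arhgef4 (0.79 ± 0.07), Myh3 (0.89 ± 0.21), Hemgn (0.80 ± 0.21) and S100a9 (0.77 ± 0.18). The liver genes Alb (1.53 ± 0.33), Afp (1.35 ± 0.37), Fga (1.15 ± 0.30) and Plg (0.77 ± 0.22) were higher there too. In limma the adjusted p ran from 9.46e-14 (Gtsf1) to 0.047 (Plg). Without the marked arrays the calls of Fga, Hemgn, Myh3 and Cck were lost, while those of Afp, Plg and Hand2 were lost without any of many single arrays. Gja5 (0.58 ± 0.08), Cited1 (0.57 ± 0.08), Tbx5 (0.49 ± 0.05) and Hand1 (0.27 ± 0.05) were higher in the left. Fgf10 (-0.42 ± 0.06), Cck (-0.25 ± 0.06) and Hand2 (-0.19 ± 0.05) were lower, and Nppa (0.65 ± 0.20) was not called (adjusted p = 0.068).

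Of the outflow tract and valve markers, 9 of 19 were lower in the left and 10 were not called (12 and 0 adjusted over the list alone, camera adjusted p = 8.15e-20). Of the genes known from the right ventricle and outflow side, 10 of 16 were lower in the left and 6 were not called (10 and 1 adjusted over the list alone, camera adjusted p = 1.92e-14). Of the genes graded towards the left ventricle, 4 of 8 were higher in the left and 4 were not called (5 and 0 adjusted over the list alone, camera adjusted p = 8.04e-09). Of the trabecular genes, 4 of 15 were higher in the left and 11 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 9.34e-08). In the Wnt, BMP, Notch and FGF list, 10 of 38 were lower in the left and 28 were not called (18 and 3 adjusted over the list alone, camera adjusted p = 1.62e-07). The mean difference was called for 541 genes (228 higher and 313 lower in the left), 8 of them at least 2-fold, with 15 of 45 lists, 6 also with an estimated correlation.

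The difference between the ventricles depended on the stage for 1065 genes (limma F-test with 5 degrees of freedom), and for 476 without the marked arrays (414 shared). The smallest p belonged to Rgs5 (F = 100.3), with a left-right difference of -1.80 ± 0.13 at E9.5 and -2.93 ± 0.13 at E12.5. Bmp4 (F = 70.45), with -3.05 ± 0.14 at E9.5 and -0.93 ± 0.14 at E12.5. Dkk1 (F = 58.92) differed by -2.41 ± 0.12 at E9.5, Isl1 (F = 41.26) by -3.00 ± 0.18 at E9.5 and 0.10 ± 0.18 at day 3, and Dlk1 (F = 45.22) by 1.33 ± 0.16 at E14.5. The count was 2719 without replicate 3 of the E18.5 left ventricle (1063 shared).

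**Figure D3:**
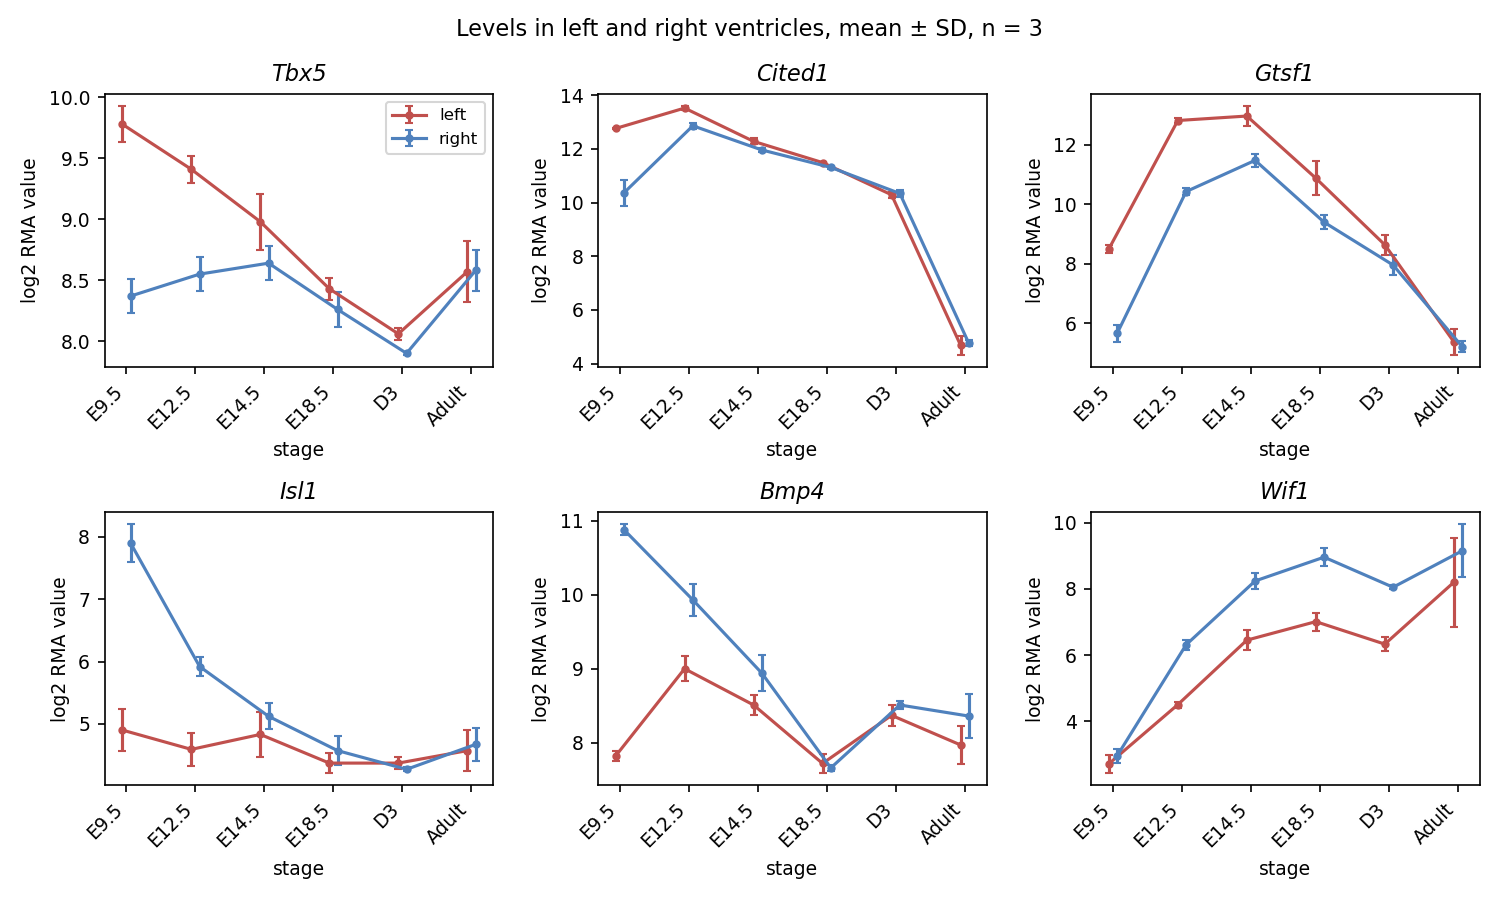
Levels (log2 RMA value) of 6 genes in left and right ventricles by stage, as mean ± SD of 3 replicates. Isl1 and Bmp4 lie apart at E9.5, by -3.00 and -3.05 left minus right, and Wif1 by -1.79 at E14.5 and -1.94 at E18.5.

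**Figure D4:**
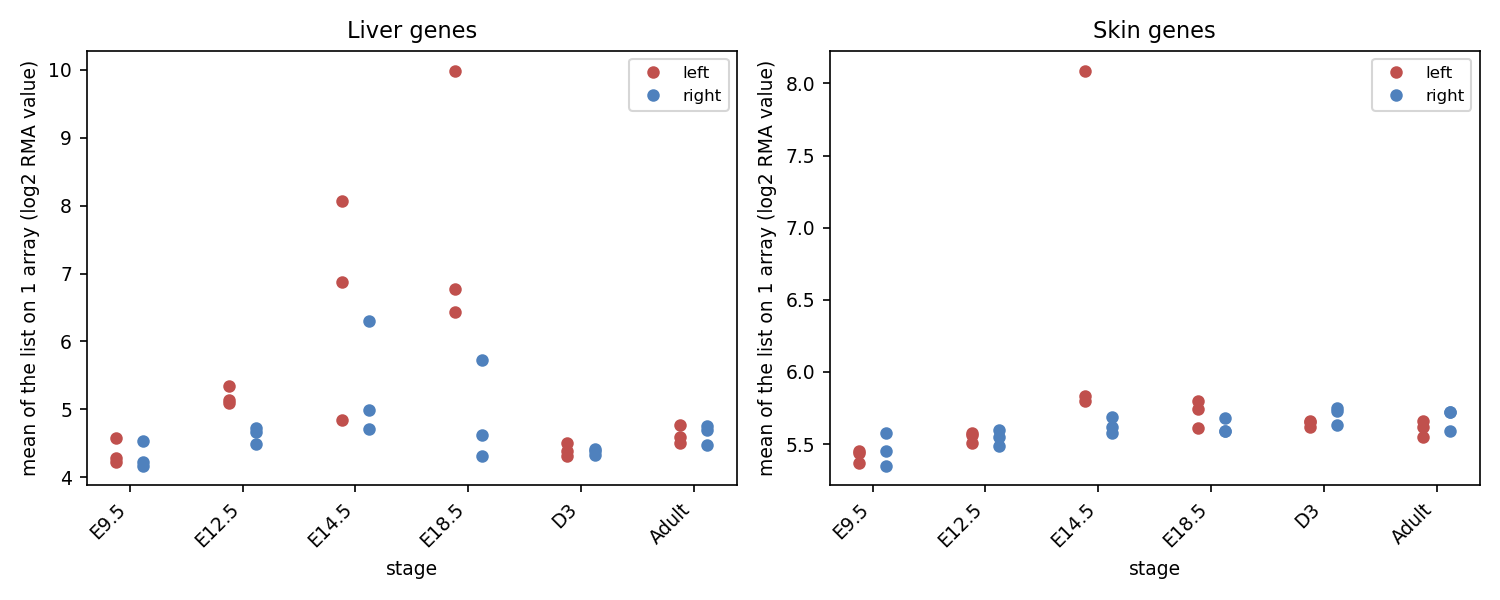
Mean level (log2 RMA value) of 15 liver genes in the left panel and 14 skin genes in the right panel, 1 point per array, by stage and ventricle. Left ventricle replicate 2 stands at 9.99 for liver genes at E18.5, and at 8.07 for liver and 8.09 for skin genes at E14.5.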

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

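The counts of other splits of the samples and the tests of replicate 2 for E14.5 and E18.5 were chosen only after the results were seen, as was a control without replicate 1. The tests of an exchange, of the other E18.5 split and of the spread were chosen before.

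The difference between left and right ventricle depended on the stage for 1065 genes by the limma F-test (adjusted p under 0.05), and F is given here for the called genes named in the text. Among genes of outflow tract, signalling and matrix, F was 100.3 for Rgs5, 70.45 for Bmp4, 58.92 for Dkk1, 41.26 for Isl1, 38.13 for Fgf8, 32.1 for Tnc, 24.67 for Tdgf1 and 22.76 for Fbln5. It was 22.5 for Masp1, 22.47 for Fgf10, 13.55 for Eln, 9.77 for Col9a1, 9.04 for Rspo3, 5.93 for Scara3, 5.53 for Robo1 and 5.33 for Shisa2. Among genes higher in the left ventricle at E9.5 or E12.5, it was 25.82 for Chn2, 25.38 for Cited1, 21.89 for Nlrp10, 21.61 for Ntn1, 19.94 for Gtsf1, 16.28 for Map3k8 and 16.16 for Tbx5. It was 11.83 for Tmem163, 10.68 for Dclk3, 10.2 for Arhgef4, 8.97 for Gja5, 7.53 for Tfcp2l1 and 7.47 for Hand1. For genes known from liver, skin and skeletal muscle, it was 4.53 for Alb, 5.93 for Fga, 4.87 for Serpina1c, 4.76 for Krtdap, 5.74 for Cdh1, 7.5 for Myh3 and 10.54 for Tnnc2. Of the other genes, F was 45.22 for Dlk1, 31.21 for Iigp1, 28.63 for Nptx2, 27.9 for Dcpp1, 16.71 for Nts and 12.37 for Cdca3. The remaining values were 11.13 for Tesc, 11.1 for Ppp1r17, 10.95 for Agtr2, 9.03 for Ndc80 and 5.59 for Cnpy4.

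More genes were called between the ventricles at E14.5 (1548) and E18.5 (900) than at E12.5 (230), with liver and skin genes among those higher in the left, but fits of only the groups compared turned this order (509 and 135 against 576). Tissue of other organs in replicate 2 of the left ventricle was excluded as the whole cause at E14.5, since without it 445 genes were called, and 25 of 96 genes at least 2-fold higher in the left lost more of their difference than they kept. At E18.5 it may account for the higher count, since 165 genes were called without this array and 322 to 2754 without any other 1 (279 against 321 at E12.5 without the marked arrays). It was excluded there as the whole cause of the 2-fold differences, of which 22 of 138 lost more than they kept (median from 1.48 to 1.15). Other tissue in several left samples and a change with age stay open, the latter untested, with mean levels of 15 liver genes at E18.5 of 6.77, 9.99 and 6.44 in the left and 5.73, 4.62 and 4.31 in the right ventricle, 6 of the 15 being also in the visceral endoderm list and 4 above the median of all values in the E12.5 ventricles (6 of 14 for skin genes).

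Another split of the 6 E18.5 arrays, left ventricle replicates 1 and 2 with right replicate 3 against the rest, called 1519 genes, more than the 900 of left against right. An exchange of left and right replicate 3 was excluded, since the score of known left minus known right ventricle genes was higher in the left of the pair by 0.22, against an SD of 0.019. Tissue of other organs in replicate 2 cannot be told apart from a loss of arrays, since without replicate 2 the other split called 1 gene and left against right 53, and without replicate 1, as a control, 2 and 165. The bound written beforehand was met, but by the control too, which is what keeps it open. No biological explanation was tested, as the labels name no further difference among these samples.

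Fewer genes were called between the ventricles at day 3 (1) and in the adult (3) than at E9.5 (637), and in fits of the 6 arrays of a stage there were 3, 0 and 586. For the latter fits a larger spread between arrays was excluded for day 3, since the 637 differences of E9.5, added to arrays of each stage, were called for 542 genes there, against 379 on the E9.5 arrays themselves. For the adult it may account for part of the low count of that fit, since 115 of them were called there, at a median SD of 0.185 against 0.13 at E9.5 and 0.121 at day 3. The test does not bear on the counts of 1 and 3, whose fit shares variances over stages. With 542 recovered but 3 called, the ventricles differed less at day 3 than at E9.5 (adult not tested).

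Each comparison of a pair of stages or ventricles had 10 splits of its 6 values, too few for a share under 0.05. For the steps from E7.5 to the adult in order, the real split called 8993, 8839, 4900, 6936, 2415, 5563, 3682 and 8872 genes, and the highest other split 49, 180, 6, 0, 1, 6, 0 and 1. No other split of a step called as many. For left against right, the real and the highest other split called 637 and 61 genes at E9.5, 230 and 0 at E12.5, 1548 and 26 at E14.5, 900 and 1519 at E18.5, 1 and 0 at day 3, and 3 and 713 in the adult. Splits with as many genes numbered 1 at E9.5, E12.5, E14.5 and day 3, 2 at E18.5 and 10 in the adult. The 713 genes of the adult came from left replicates 1 and 3 with right replicate 1 against the rest. Another structure of samples or their larger spread may underlie this. In adult left replicates 1 to 3 the score of known left minus right genes was 3.24, 3.57 and 3.05. In the right it was 2.93, 3.56 and 3.55, against the labels in replicate 3. Its left list shares Nppa and Gja5 with the atrial list, highest in right replicate 3 (mean 8.99). No cause or exchange was tested. For the mean of 6 stages (541 genes, highest other 560), 2 of 100 splits called as many, so chance was unlikely. For the F-test (1065, highest 2717) 3 did, but shuffled sides cannot test stage dependence.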

How the results depend on the processing

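Fits without the marked arrays were chosen after seeing the data, and all other alternatives before. For 1576 results of named genes, 23486 values kept direction and side of the threshold, 2105 were no longer called, 15 became called and 22 turned in sign. Counts stayed within 1.5 times the main value in 349 cases and moved further in 63, and the cause was not tested unless it is named. A stricter threshold lowers a count by construction. Signal over background was not in the values, so it is open how far dim genes limit the calls. The housekeeping scaling, the filter on dim genes, the trended robust eBayes and the mean of probe sets moved no total by more than 1.5 times. The housekeeping scaling moved its parts further, with rises from 4414 to 6809 and falls from 4579 to 2977 at the E7.5 step, 2337 to 1442 and 2563 to 5153 at the E9.5 step, and rises from 4066 to 7460 at the adult step.

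In fits of only the groups compared, left against right called 576 genes at E12.5, 509 at E14.5, 135 at E18.5, 3 at day 3 and 0 in the adult (limma, 273 at an unadjusted p under 0.05). With every probe set tested, the adult count was 7. With at least a 2-fold difference, the steps from E7.5 on had 2119, 1919, 528, 909, 188, 506, 285 and 1829 genes, and left against right 139 at E9.5, 86 at E12.5, 117 at E14.5, 149 at E18.5, 0 in the adult (limma, 1127 at an unadjusted p under 0.05 and any size) and 8 for the mean, with no value for the F-test. At an adjusted p under 0.01, the E9.5, E14.5 and day 3 steps had 3249, 1239 and 2145 genes, left against right 342 at E9.5, 138 at E12.5, 523 at E14.5, 279 at E18.5 and 253 for the mean, and the F-test 396. The E14.5 step had 1175 genes with left ventricles only and 3695 with all 45 arrays as 15 groups. With an estimated correlation, 51 list results were called over the stage steps (138 without) and 18 over the ventricle comparisons (82 without). By fry, which tests a list by itself, they were 217 and 41. Without the marked arrays, left against right called 422 genes at E9.5, 551 at E14.5 and 279 at E18.5, and the F-test 476.

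With the replicate block, left against right called 2 genes at day 3 (1 without) and 7 in the adult (3 without, 1 shared), and 289 at E12.5 (230 without), where the numbers paired the samples. At day 3 the correlations of same-numbered ventricles were 0.167, 0.027 and 0.091 over all genes, so that by this measure whether the numbers paired them depended on the genes used. In the adult they were 0.223, 0.33 and -0.096, at E9.5 0.257, 0.317 and 0.071, at E14.5 -0.119, -0.139 and 0.11, and at E18.5 -0.236, -0.155 and -0.318. The block moved no other count by over 1.5 times, with 711 at E9.5, 1271 at E14.5, 750 at E18.5, 547 for the mean, 914 for the F-test, and 142 and 80 list results. At E12.5 it changed the 3 list calls given for that stage. Across stages a number names different pools, so the block of the steps pairs nothing.

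Without single arrays, the E14.5 step called 1344 to 2030 genes. Left against right called 357 to 745 at E9.5, 129 to 172 at E12.5, 445 to 2148 at E14.5, 165 to 2754 at E18.5, 1 to 2 at day 3, 4 to 98 in the adult and 421 to 718 for the mean. The F-test ranged from 738 to 2719, without replicates 2 and 3 of the E18.5 left ventricle, and the list results from 136 to 144 and from 77 to 88. Arrays left out alone leave 2 in a group, which are taken to vary like the other groups.

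Gene results that turned in sign were, with the mean of probe sets, Gnas at E12.5 (-0.26), Dlst (-0.12) and Hspa8 (-0.08) at day 3, Igf2bp1 in the adult (-0.37) and H2-D1 between the ventricles at E18.5 (0.41). With left ventricles only they were Tnc (0.11) and Egln3 (-0.12) at E12.5 and Sema3c (0.13) at E14.5. With right ventricles only they were Tnc (0.72) and Dlk1 (0.27) at E9.5, Col6a3 (-0.12), Eln (-0.98), Tnc (-0.01) and Nrp2 (-0.1) at E14.5, and Msln (-0.02), Cdh1 (0.19) and Myh3 (0.15) at E18.5. At day 3 they were Upk3b (0.05), Msln (0.31), Krt7 (0.19), Cd3d (0.15) and Hspa8 (-0.06). Here 1 ventricle went against the mean of both.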

Other observations

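The count of genes shared between stages was chosen only after the results were seen. In the list of circadian clock genes more members rose than fell at 3 steps in a row, and the call of the list was lost with an estimated correlation at each. From E9.5 to E12.5, 7 of 15 rose and 8 were not called (camera adjusted p = 0.016, adjusted p = 0.103 with an estimated correlation), with Hlf (1.74 ± 0.14) and Tef (0.75 ± 0.09) among the rises. From E12.5 to E14.5, 5 of 15 rose, 1 fell and 9 were not called (camera adjusted p = 0.021, adjusted p = 0.116 with an estimated correlation). From E14.5 to E18.5, 6 of 15 rose and 9 were not called (camera adjusted p = 0.009, adjusted p = 0.078 with an estimated correlation), led by Npas2 (1.94 ± 0.19). At the same step, of the targets and receptors of thyroid hormone and glucocorticoids, 5 of 12 rose and 7 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.002), led by Klf9 (2.01 ± 0.12) and Zbtb16 (1.05 ± 0.12). From E18.5 to day 3, Per1 (-1.37 ± 0.13) and Fkbp5 (-0.91 ± 0.11), both known to respond to glucocorticoids, fell.

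Genes called between the ventricles at E9.5 and again at E12.5 in the same direction numbered 29 higher in the left and 57 higher in the right, where independent lists of these sizes share 1.26 and 2.51. At E9.5 and E14.5 they numbered 24 and 30 (15.4 and 11.7 by independence), at E9.5 and E18.5 12 and 13 (10.3 and 5.76), and at E12.5 and E14.5 17 and 45 (2.67 and 7.13). At E12.5 and E18.5 they were 8 and 20 (1.79 and 3.53), and at E14.5 and E18.5 41 and 34 (21.9 and 16.4).

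Levels of the X-linked gene Xist and the Y-linked gene Eif2s3y were read as a check. In adult replicate 2, Xist stood at 10.25 in the left and 10.79 in the right and Eif2s3y at 3.53 and 2.85. In day 3 replicate 2, a sample of 1 heart by the labels, Xist stood at 10.63 and 10.45 while Eif2s3y stood at 8.26 and 8.03. At E14.5, Xist was 6.01 in right ventricle replicate 2 and 10.18 in left ventricle replicate 2.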
